A study of Priestia megaterium with 4 samples.

How the data were processed

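Total RNA from Priestia megaterium CL-1 was extracted with a Qiagen RNeasy kit, depleted of ribosomal RNA with QIAseq FastSelect, made into stranded libraries with a QIAseq kit and checked on a Bioanalyzer, per the labels' protocols. The 4 libraries fall into 2 groups of 2, cells without salt stress and cells at 8% salt. The submitters' processing notes name Trim Galore, Bowtie2, featureCounts and DESeq2, without versions or roles. The genome and annotation behind the locus tags, the strand setting and the handling of reads that map to several places are not given in the sources used here.

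The deposited values are log2 values in 1 table of 4775 features by 4 columns, with a lowest value of exactly 2. They have the form log2(read count divided by a size factor, plus 4). After removing the log and the 4, 100% of the values in every library were whole multiples of a library's own step within a tolerance of 0.01. The size factors those steps give (1.51, 1.29, 0.672 and 0.772 for C0, C1, T1 and T2) are those of the median-of-ratios method computed from the recovered reads. The design written before the data were examined had assumed plain normalised values, so the deposited log2 values were first turned back into normalised counts. The columns carry no sample name, and their letters C and T gave the group. A symbol stands beside 1085 features, 3690 have a product name and locus tag only, and 99 symbols belong to more than 1 feature. Such genes are given with their locus tag, and counts of near-identical copies are uncertain because reads may be shared between them.

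Reads assigned to features numbered 4655174 and 4873998 in the control libraries C0 and C1 and 6740474 and 6303394 in the salt libraries T1 and T2. Totals of normalised counts were 3073190, 3770260, 10032100 and 8162820. Genes at 0 reads numbered 1, 1, 14 and 11. An error on normalised counts is the SD of the 2 libraries of a group, which includes counting error.

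Genes with a normalised count of at least 10 in at least 2 libraries were kept (4738; 37 were left out). The main test was limma 3.58.1 in R 4.3.3 with an intensity trend on log2(normalised count + 1), with Benjamini-Hochberg adjustment over all genes kept and a threshold of 0.05. Fold changes are on that log2 scale, which understates the change of low genes, with the moderated standard error from limma. That error draws a gene's own spread towards the trend of genes at its level, so in abundant genes it can be far wider than the libraries' spread. Of 33 gene lists fixed from product names and symbols before the data were examined, 30 had at least 4 genes kept and were tested with camera at a preset correlation of 0.01, adjusted over the 30 lists. Members of each list were also adjusted over the list alone. Ribosomal protein, aminoacyl-tRNA synthetase and biofilm lists were too small and are not analysed here.

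Genes were named by a rule fixed before the data were examined. It took the 12 largest increases and 12 largest decreases past the threshold with both salt libraries on the same side of both controls, a mean of at least 50 in the higher group and a symbol or informative product name. It added up to 4 members of each list with the largest change, all members of the 2 compatible solute lists, and sigB, sigA and spo0A where present, for 146 genes in all. Genes outside the rule are said to be so where they are named.

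Alternatives were a pseudocount of 0.5 or 8, no filter, a filter of 50, TMM scaling (own code), equal library totals, no intensity trend, each library left out in turn, camera with an estimated correlation, and the directional fry test. The log2 values as deposited, and limma voom on the recovered reads, were added after the data were seen. Where a library was left out, the lone library of its group was assumed to vary like the other pair. The test was checked on simulated counts of 4733 genes, with gene means over all 4 libraries, the 4 size factors and 1 dispersion of 0.029. Of 100 genes changed 2-fold 71% were recovered, of 100 changed 4-fold 100% were, and 6 of 4533 unchanged genes were called. Simulated genes varied independently, with no shared spread along the axis between the groups. The real libraries and share of changed genes differ from this, so the simulation does not measure false calls there. Tests of level used 10000 random lists drawn in 20 bins of the mean level over all libraries or, in a repeat, over the controls, and the test of gene order 9999 shuffles. Other steps used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. No reference genome was used here, so coordinates, gene lengths and GC content were not analysed.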

Results

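RNA was sequenced from 4 libraries of the bacterium Priestia megaterium CL-1, a spore-forming rod of the Bacillaceae. By the labels, 2 libraries came from cells grown without salt stress and 2 from cells at 8% salt; the salt itself is not named. The comparison asks which genes change their transcript level under salt stress. Each of the 4775 features in the table carries a product name with a gene symbol or a locus tag. The organism and strain of the annotation that gave these names are not stated in the sources used here, so a name such as enterotoxin or exosporium protein is that of the table and may not describe this organism's gene. All but 1 and 1 features in the control libraries and 14 and 11 in the salt libraries held reads, so nearly every feature in the table was covered. Only 1 feature matched the ribosomal protein list and 0 the aminoacyl-tRNA synthetase list, so the table may not hold the whole annotation. Whether the labelled species is that of the annotation was not tested. The 2 control libraries held 4655174 (C0) and 4873998 (C1) reads assigned to features, and the 2 salt libraries held 6740474 (T1) and 6303394 (T2). The groups were read from the letters of the column names, C for control and T for treated. If that reading were reversed, every direction given here would turn. Nothing in the labels says that the libraries came from separate cultures, so p-values rest on the spread between these libraries, pooled over genes of similar level, which may be technical.

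By camera at its preset correlation 15 of 30 lists were called, and 8 of them kept their call and the sign of their median in every refit. Cold shock, general stress, oxidative stress, tricarboxylic acid cycle, ATP synthase and cell division genes were higher at 8% salt, and sporulation and branched-chain amino acid synthesis genes lower. Of these lists, only cold shock, cell division, sporulation and branched-chain amino acid synthesis had medians beyond random lists matched on expression level, with both choices of level. With an estimated correlation 0 of 30 lists passed (camera adjusted p = 0.70 for each of the 8). That form of camera rests on the few residual degrees of freedom of 4 libraries in 2 groups. It had little power to call any list, so its failures given here say little about single lists. Of 4738 genes tested, 3809 (80.4%) differed between the groups at an adjusted p below 0.05 in limma, 1941 of them higher and 1868 lower at 8% salt. At least 2-fold changes were called for 1480 higher and 1227 lower genes, and with equal totals for 216 higher and 2762 lower. Among genes that met the naming rule (past the threshold, an informative name, a mean of at least 50 in the higher group and both salt libraries on one side of both controls), the largest increases were in cspB (FORC47_RS18160), a cold shock protein gene, at 3.18 ± 0.62 (SE) on the log2 scale, in bfmBAB, which encodes part of the branched-chain keto acid dehydrogenase, at 3.11 ± 0.53, and in the beta-lactamase gene bla at 3.05 ± 0.34. The largest decreases under that rule were in a lipoprotein gene (FORC47_RS04585) at -4.87 ± 0.37, a Gly-Xaa-Xaa repeat protein gene (FORC47_RS19130) at -4.26 ± 0.37 and a BclA-related collagen-like exosporium gene (FORC47_RS24375) at -4.14 ± 0.44, the last at -3.51 without T1 and -4.77 without T2. The lipoprotein gene FORC47_RS04585 held only 1.49 and 2.59 normalised counts in T1 and T2, so its fold change and rank rest on the pseudocount of 1.

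**Figure D1:**
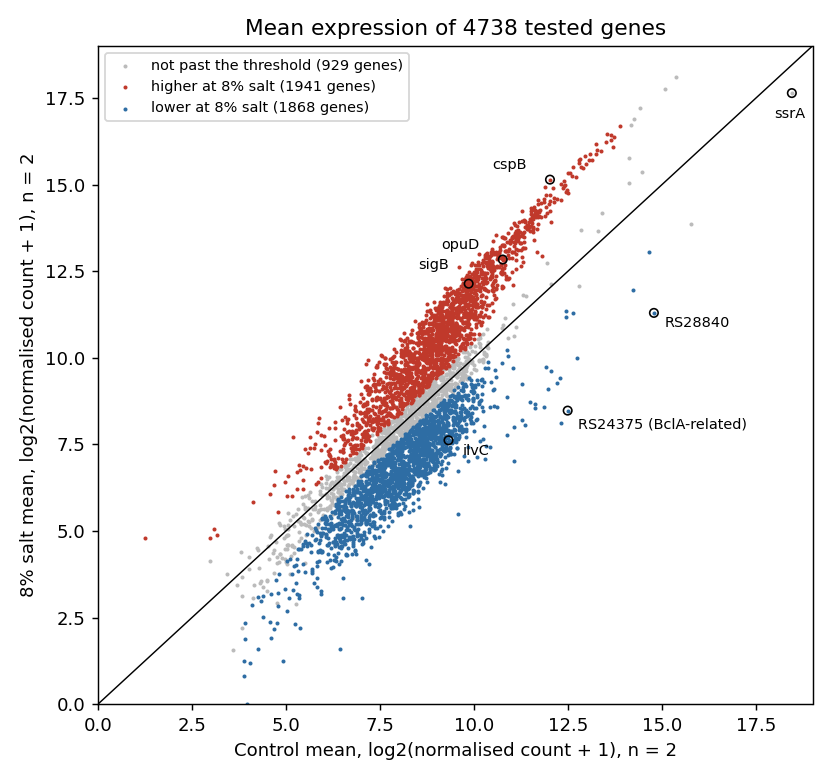
Mean log2(normalised count + 1) of each of 4738 tested genes in the 2 control libraries (horizontal axis) and the 2 libraries at 8% salt (vertical axis); each point is a gene, the line marks equal values, and circles mark the genes named. Risen genes (1941) lie above the line and fallen genes (1868) below it, and the 474 genes with the highest mean level have a median log2 fold change of 2.30 against -1.11 in the 474 with the lowest.

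The other genes among the 12 largest increases were acpP (acyl carrier protein, 3.05 ± 0.49), leucine dehydrogenase (FORC47_RS21500, 3.02 ± 0.82), a CsbD family gene (FORC47_RS18740, 3.01 ± 0.46), yqiS (phosphate butyryltransferase, 2.99 ± 0.71) and entFM (named an enterotoxin, 2.97 ± 0.76). They also held a ferritin-like gene (FORC47_RS05210, 2.97 ± 0.67), a dihydrolipoamide acetyltransferase gene (FORC47_RS21475, 2.95 ± 0.68), a general stress protein gene (FORC47_RS05175, 2.93 ± 0.42) and rpoA, the alpha subunit of RNA polymerase, at 2.93 ± 1.03. Of these 12 calls, 7 were lost without salt library T1. Those were cspB (adjusted p = 0.0535), FORC47_RS21500 (0.19), yqiS (0.127), entFM (0.165), FORC47_RS05210 (0.111), FORC47_RS21475 (0.14) and rpoA (0.311). All of these except cspB were also lost without salt library T2, at adjusted p from 0.1 to 0.288. The fold changes themselves stayed close, from 2.74 (rpoA) to 2.97 (yqiS) without T1 and from 2.99 (FORC47_RS21475) to 3.18 (entFM) without T2. Without C0 and without C1, acpP was at 2.44 and 3.66 and rpoA at 2.30 and 3.56. The call of rpoA was also lost with equal totals (0.122), with TMM scaling (0.0637) and without the filter (0.0583). The other 9 of the 12 largest decreases were in exsG, an exosporium gene (-4.03 ± 0.42), an exosporium leader peptide gene (FORC47_RS06230, -4.13 ± 0.37), a collagen-like gene (FORC47_RS17045, -3.34 ± 0.28), a cell wall anchor gene (FORC47_RS02325, -3.27 ± 0.40), a DinB family gene (FORC47_RS16115, -3.10 ± 0.29), a DnaD domain gene (FORC47_RS04880, -3.05 ± 0.39), a septum formation initiator gene (FORC47_RS14230, -3.03 ± 0.48), a lytic transglycosylase gene (FORC47_RS28820, -3.45 ± 0.47) and an ArdC-like gene (FORC47_RS28785, -3.05 ± 0.44). Without T1 and without T2, FORC47_RS28820 was at -2.75 and -4.16, FORC47_RS28785 at -2.43 and -3.68, and FORC47_RS14230 at -2.35 and -3.71. In T1 and T2, exsG held only 4.47 and 10.4 normalised counts and FORC47_RS14230 5.95 and 16.8. The pseudocount of 1 therefore also bears on the fold changes and ranks of these genes. All 12 decreases stayed past the threshold when any one library was left out.

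Transporters for compatible solutes, the small molecules that balance osmotic pressure, had no common direction. The glycine betaine carrier gene opuD rose in both of its copies, from 1738 ± 521 (SD, n = 2) to 7308 ± 1065 normalised counts in FORC47_RS02915 (2.10 ± 0.34) and from 2214 ± 776 to 8940 ± 1434 in FORC47_RS26990 (2.05 ± 0.38). The sodium/proline symporter gene putP (FORC47_RS18790) went from 3220 ± 1484 to 17926 ± 3571 (2.54 ± 0.50, adjusted p = 0.00648; 0.0526 without T1), while the 3 genes of a glycine betaine/proline ABC transporter fell. These were the substrate-binding protein (FORC47_RS14250, -2.18 ± 0.33), the ATPase (FORC47_RS14245, -2.14 ± 0.31) and the permease (FORC47_RS14240, -1.62 ± 0.27). The second putP (FORC47_RS06355) stood at 0.67 ± 0.19, turned to -0.74 when libraries were set to equal totals, and lost its call in each fit without a library (adjusted p = 0.111 without C0, 0.0555 without C1, 0.169 without T1 and 0.0684 without T2). Of the 7 genes of this list, 4 rose and 3 fell, also adjusted over the list alone, and with equal totals 3 rose and 4 fell, while without T1 only 2 rose. The list as a whole was not apart from other genes (camera adjusted p = 0.844).

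Genes listed for making compatible solutes were also divided. By its product name the listed treP is a trehalose uptake component (phosphotransferase system EIIBC), not a synthesis enzyme. The pyrroline-5-carboxylate reductase gene proC, the last step of proline synthesis, rose in FORC47_RS01125 (2.31 ± 0.35, adjusted p = 0.00391), and its relative proI fell (-1.91 ± 0.36). A second proC (FORC47_RS15265) stood at 1.24 ± 0.19 and at -0.17 with equal totals, and another (FORC47_RS12315) fell (-0.92 ± 0.24). The trehalose phosphotransferase gene treP rose from 4744 ± 1859 to 24483 ± 4536 normalised counts (2.41 ± 0.53), with adjusted p = 0.123 without T1 and 0.0837 without T2. The glutamate-5-semialdehyde dehydrogenase gene (FORC47_RS15250) stood at 0.76 ± 0.18, at -0.65 with equal totals and at adjusted p = 0.0648 without C0. The glutamate 5-kinase gene proB did not pass (log2 fold change 0.38 ± 0.19, adjusted p = 0.113; -1.03 with equal totals). In this list 4 of 7 genes rose and 2 fell, with the same counts adjusted over the list alone, while with equal totals 2 rose and 4 fell (camera adjusted p = 0.427). Between libraries of one group, putP (FORC47_RS18790), opuD and treP were higher in C1 than in C0 and higher in T1 than in T2.

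**Figure D2:**
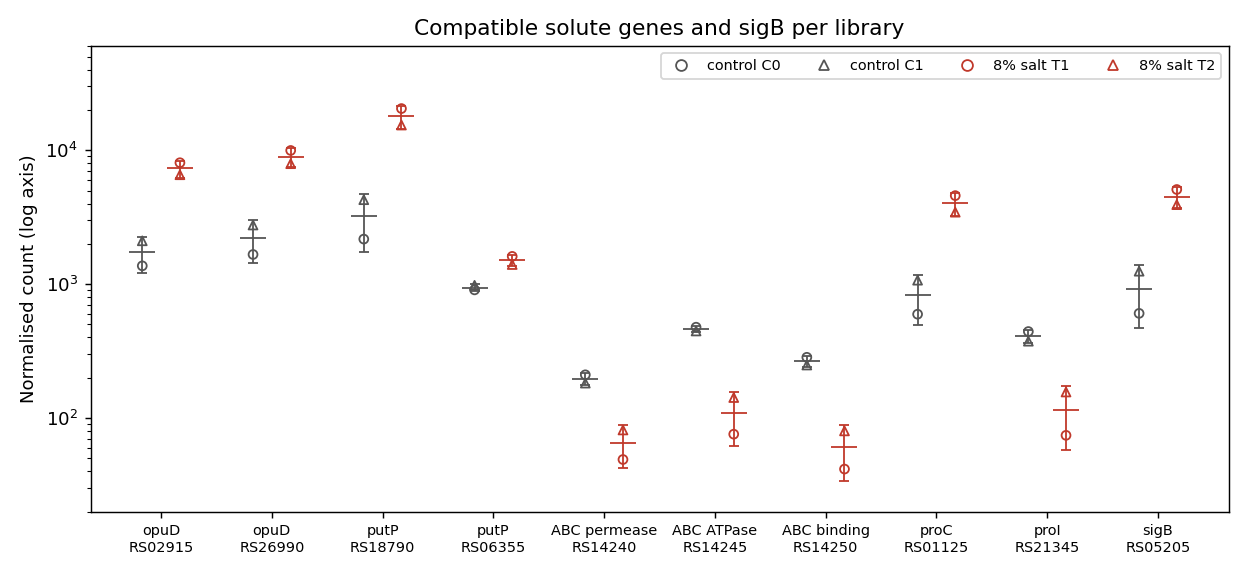
Normalised counts (log axis) of the 7 genes of the compatible solute uptake list, proC (FORC47_RS01125), proI and sigB in control library C0 (grey circle) and C1 (grey triangle) and in salt library T1 (red circle) and T2 (red triangle); horizontal bars are group means and error bars are 1 SD of 2 libraries. Both opuD copies and sigB are higher in both salt libraries than in both controls, the ABC transporter genes are lower, and putP (FORC47_RS06355) differs least of the genes drawn (log2 fold change 0.67).

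Ion transport genes showed no common direction. Among 12 potassium transport genes, 2 rose and 4 fell, but only 1 fell without C0 and 1 without C1. A TrkA family gene (FORC47_RS20515) stood at 1.59 ± 0.24 and a TrkH family gene (FORC47_RS06850) at 1.33 ± 0.22. With equal totals 10 of the 12 fell, the TrkH gene stood at -0.0762 and the TrkA gene was not past the threshold (adjusted p = 0.325). Another TrkH family gene (FORC47_RS06805) fell by 1.20 ± 0.21, and kdpF, a subunit of the high-affinity potassium pump, was at -1.37 ± 0.40, with adjusted p = 0.332 without C0 and 0.275 without C1. Of 13 sodium-proton antiport genes, 5 rose and 3 fell, and with equal totals 1 rose and 9 fell. One cation:proton antiporter gene (FORC47_RS08350) was at 2.43 ± 0.50 (adjusted p = 0.0667 without T1), another (FORC47_RS04360) fell (-1.86 ± 0.24), and so did an antiporter (FORC47_RS26110, -1.39 ± 0.37) with its neighbouring regulatory subunit (FORC47_RS26115, -2.02 ± 0.30). The counts at the deposited scaling were the same adjusted over each list alone. Camera gave an adjusted p of 0.531 for the potassium list and 0.702 for the antiport list.

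Genes of the general stress response, which the sigma factor SigB controls, rose: 8 of 10 were higher and 1 was lower (8 and 2 with equal totals). The gene sigB went from 927 ± 455 to 4505 ± 825 normalised counts (2.36 ± 0.40, adjusted p = 0.00459), and CsbD family genes rose by 3.01 ± 0.46 (FORC47_RS18740) and 2.79 ± 0.36 (FORC47_RS05180). Of 20 chaperone and protease genes, which refold or degrade damaged proteins, 17 rose and 2 fell (15 and 3 with equal totals, and 10 rose without T1), with hslV at 2.86 ± 0.43, hslU at 2.84 ± 0.53 and grpE at 2.52 ± 0.48. The trigger factor gene tig was at 2.80 ± 0.65, with adjusted p = 0.107 without T1 and 0.0721 without T2. All 7 cold shock genes rose, and 4 of them with equal totals, among them cspD (FORC47_RS25105, 2.64 ± 0.49; FORC47_RS11780, 2.47 ± 0.36) and a second cspB (FORC47_RS08305, 2.48 ± 0.29). Of 31 genes for oxidative stress defence, 23 rose and 6 fell, while with equal totals 10 rose and 9 fell (median 1.53, or 0.12 with equal totals). The superoxide dismutase gene sodA (FORC47_RS22080) rose by 2.85 ± 0.56 and the thioredoxin gene trxA (FORC47_RS23270) by 2.70 ± 0.42. The peroxidase genes ahpC (2.77 ± 0.70) and ahpF (2.73 ± 0.84) lost their calls without T1 (adjusted p = 0.133 and 0.253) and without T2 (0.0958 and 0.218), and ahpF also with equal totals (0.0712). The size of these changes rested on which control was used: without C0 and without C1, ahpC was at 2.10 and 3.44, ahpF at 2.12 and 3.33, sodA (FORC47_RS22080) at 2.24 and 3.46, and tig at 2.19 and 3.42.

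Against all other genes, camera gave adjusted p-values of 0.0216 for the SigB list, 0.00845 for chaperones, 0.00845 for cold shock and 0.00845 for oxidative stress. With an estimated correlation these lists had an adjusted p = 0.70 each. The chaperone list also failed without T1 (adjusted p = 0.0642) and without T2 (0.0916). Adjusted over the list alone, 3 rather than 2 chaperone genes fell and the other counts were the same. The controls differed along the same direction: C1 exceeded C0 by a median of 0.79 on the log2 scale in the SigB list, 0.78 in chaperones, 0.72 in cold shock and 0.43 in oxidative stress genes.

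Of 15 glycolysis genes 13 rose and 2 fell (9 and 2 with equal totals), but only 5 rose without T1 and 7 without T2, with ptsH, a phosphotransferase carrier, at 2.75 ± 0.47. Eno (2.69 ± 0.76), gpmI (2.74 ± 0.80) and fructose-bisphosphate aldolase (FORC47_RS27550, 2.75 ± 0.72) were past the threshold only with both salt libraries. Their adjusted p was 0.211, 0.223 and 0.174 without T1, and 0.19, 0.205 and 0.129 without T2; with equal totals eno (0.0508) and gpmI (0.0559) also failed. Without C0 and without C1, ptsH was at 2.15 and 3.36, eno at 2.11 and 3.28, gpmI at 2.16 and 3.33, and the aldolase at 2.15 and 3.35. Of 16 genes of the tricarboxylic acid cycle 14 rose and 0 fell (12 and 2 with equal totals). Isocitrate dehydrogenase (icd) rose by 2.50 ± 0.34 and the 2-oxoglutarate dehydrogenase subunit gene odhB by 2.47 ± 0.36. Its partner odhA (2.47 ± 0.46) was lost without T1 (adjusted p = 0.0732) or T2 (0.057), and the succinate dehydrogenase gene sdhA (2.46 ± 0.44) without T1 (0.0526).

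Genes of the ATP synthase rose in 10 of 12 cases and fell in 1 (8 and 2 with equal totals), with atpE at 2.56 ± 0.41, atpF at 2.53 ± 0.39, atpG at 2.51 ± 0.43 and atpH at 2.45 ± 0.39. Of 33 respiratory chain genes 23 rose and 3 fell, a direction that rests on the scaling, since the median of 0.73 became -0.68 with equal totals, where 10 rose, 17 fell and the list did not pass camera (adjusted p = 0.0555). The list does not hold the 11 NADH-quinone oxidoreductase genes, looked at after their values were seen, all of which fell. The aa3 quinol oxidase genes stood out at 2.45 ± 0.40 (FORC47_RS03695, subunit II) and 2.41 ± 0.34 (qoxC), and a cytochrome c biogenesis gene (FORC47_RS18870) at 2.40 ± 0.34. Subunit gene qoxB (2.29 ± 0.53) had an adjusted p = 0.143 without T1 and 0.112 without T2. Camera gave adjusted p-values of 0.0412 for glycolysis, 0.00198 for the tricarboxylic acid cycle, 0.0126 for the ATP synthase and 0.00198 for the respiratory chain. With an estimated correlation each had an adjusted p = 0.70, and glycolysis failed without T1 (adjusted p = 0.289) and without T2 (0.303). Counts adjusted over each list alone were the same. Within the control group, C1 exceeded C0 by a median log2 difference of 1.17 in glycolysis, 0.54 in the cycle, 0.88 in the ATP synthase and 0.15 in the respiratory chain.

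Sporulation and germination genes, which also stand for forespores and mother cells that a culture can hold, fell: 99 of 137 were lower, 27 were higher and 11 did not pass, with the same counts adjusted over the list alone. With equal totals 114 were lower and 4 higher. The list's median was -1.25 (camera adjusted p = 4.53e-05; adjusted p = 0.70 with an estimated correlation). The YjcZ family sporulation gene FORC47_RS04995 fell from 308 ± 27.0 to 46.2 ± 31.7 normalised counts (-2.89 ± 0.49) and its relative FORC47_RS09960 fell by 2.47 ± 0.37. The YlmC/YmxH family gene FORC47_RS19615 (-2.54 ± 0.34) and a sporulation lipoprotein gene (FORC47_RS14045, -2.42 ± 0.43) fell as well. Without T1 and without T2, FORC47_RS04995 was at -2.15 and -3.63 and FORC47_RS14045 at -1.76 and -3.07. The gene for Spo0A, the master regulator of entry into sporulation, rose instead, from 792 ± 213 to 2763 ± 523 (1.82 ± 0.28, adjusted p = 0.00391). In this list C1 was below C0 in 102 of 137 genes and T1 was below T2 in 101.

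All 13 genes for branched-chain amino acid synthesis fell, also adjusted over the list alone. They included ilvB (-1.83 ± 0.22), ilvE (-1.82 ± 0.19), ilvC (-1.73 ± 0.22) and leuD (-1.70 ± 0.33), and the list's median was -1.49 (camera adjusted p = 0.00117; adjusted p = 0.70 with an estimated correlation). All 13 were also lower in C1 than in C0 and lower in T1 than in T2. Arginine synthesis genes fell in 6 of 9 cases and rose in 2 (8 and 0 with equal totals), with argJ at -1.65 ± 0.19, argH at -1.34 ± 0.34, argC at -1.18 ± 0.24 and argB at -1.16 ± 0.17, and the list did not pass camera (adjusted p = 0.282). Histidine synthesis genes rose in 7 of 11 cases (6 adjusted over the list alone), and in only 2 without C0 and 2 without C1. The direction turned with equal totals, where 0 rose, 9 fell and the median went from 0.43 to -0.98. The genes hisB (0.84 ± 0.17) and hisC (FORC47_RS07860, 1.22 ± 0.21) turned to -0.57 and -0.18. Likewise hisC (FORC47_RS15080, 0.62 ± 0.12) and hisH (0.54 ± 0.14) turned to -0.78 and -0.87, and lost their calls without C0 (adjusted p = 0.11 and 0.141) and without C1 (0.0922 and 0.151). With TMM scaling hisH had an adjusted p = 0.0816. The list passed camera (adjusted p = 0.0412; adjusted p = 0.70 with an estimated correlation), but not with TMM scaling (adjusted p = 0.144), with equal totals (0.423) or when any one library was left out (adjusted p from 0.055 to 0.561).

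Cell wall and cell division genes were mostly higher at the deposited scaling. Of 50 cell wall genes 36 rose and 7 fell, a direction that rests on the scaling, since the median of 1.36 became -0.0446 with equal totals, where 18 rose and 19 fell. The teichoic acid D-alanylation genes dltC (2.79 ± 0.43), dltA (2.54 ± 0.45) and dltB (2.43 ± 0.39) and the rod shape gene mreC (2.68 ± 0.43) led this list, with dltC at 2.18 without C0 and 3.40 without C1. Of 16 cell division genes 14 rose and 1 fell (2 fell adjusted over the list alone, and 11 rose and 2 fell with equal totals), with gpsB at 2.54 ± 0.37, ftsA, listed as a pseudogene, at 2.53 ± 0.49 and minC at 2.52 ± 0.38. Fatty acid and phospholipid genes rose in 19 of 30 cases and fell in 8 (14 and 11 with equal totals), with accC at 2.74 ± 0.51, fabI at 2.51 ± 0.50 and fabG (FORC47_RS19850) at 2.50 ± 0.46. Camera gave adjusted p-values of 0.00198, 0.00393 and 0.118 for the 3 lists, and adjusted p = 0.70 with an estimated correlation for each. The fatty acid list passed without C0 (adjusted p = 0.0392), without C1 (0.0132) and with equal totals (0.000355). The median of C1 minus C0 was 0.40, 0.70 and 0.41 in these lists.

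Motility and chemotaxis genes rose in 33 of 44 cases and fell in 6, again relative to the deposited scaling, with a median of 1.23 that became -0.18 with equal totals, where 6 rose and 16 fell. Without C0, 3 fell. A flagellin gene (FORC47_RS08600) went from 533 ± 281 to 2563 ± 25.6 normalised counts (2.37 ± 0.39), and the genes for the motor switch proteins FliN (FORC47_RS08610) and FliG (FORC47_RS08480) and a hook-associated protein gene (FORC47_RS08500) rose by 2.39 ± 0.31, 2.06 ± 0.35 and 2.09 ± 0.34. Of 5 polyhydroxyalkanoate genes, which serve to store carbon as polyester granules, 4 rose and 0 fell (5 rose adjusted over the list alone), with a median of 1.07 and -0.34 with equal totals, where 0 rose and 2 fell. There phaP (1.51 ± 0.17) fell short of the threshold (adjusted p = 0.609), and phaR (1.39 ± 0.15), acetoacetyl-CoA reductase (FORC47_RS06835, 1.07 ± 0.17) and phaQ (0.59 ± 0.14) turned to -0.0215, -0.34 and -0.82. The gene phaQ was also lost without C0 (adjusted p = 0.126), without C1 (0.089) and with TMM scaling (0.0515). Camera gave an adjusted p of 0.0018 for motility and 0.0412 for polyhydroxyalkanoates, and adjusted p = 0.70 with an estimated correlation for both. The polyhydroxyalkanoate list failed with equal totals (adjusted p = 0.691) and without any one library (adjusted p from 0.0663 to 0.239). C1 exceeded C0 in 36 of 44 motility genes and in all 5 polyhydroxyalkanoate genes.

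**Figure D3:**
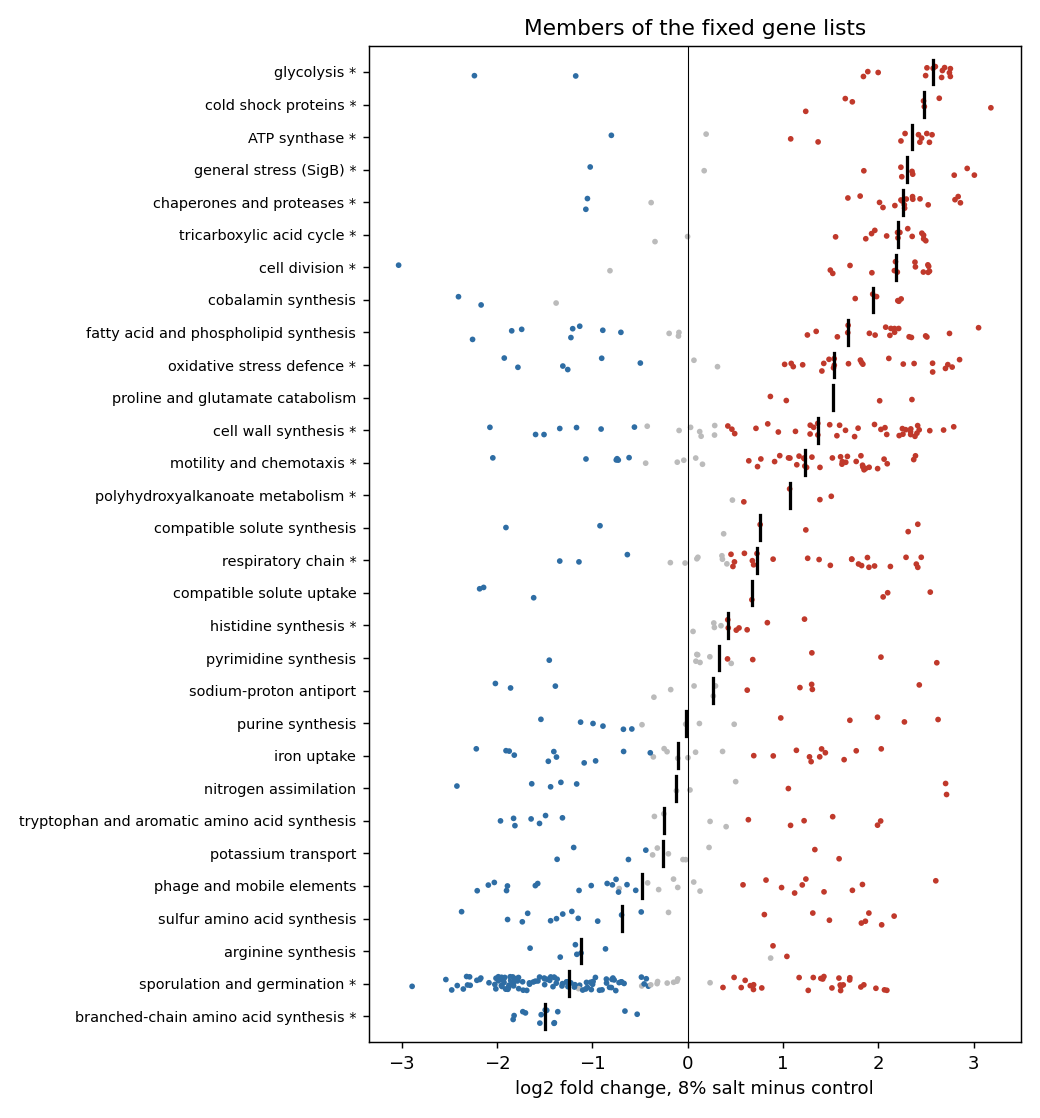
Log2 fold change (8% salt minus control, horizontal axis) of every tested member of the 30 fixed gene lists with at least 4 tested genes; red and blue points passed an adjusted p of 0.05 as higher and lower, grey points did not, black bars are list medians, and asterisks mark the 15 lists called by camera at its preset correlation. Medians run from -1.49 in branched-chain amino acid synthesis to 2.57 in glycolysis at the deposited scaling; with equal totals 9 medians change sign.

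The remaining lists did not pass camera. Proline and glutamate catabolism came closest, with 4 of 4 genes higher, also adjusted over the list alone, and with equal totals 2 higher and 1 lower (camera adjusted p = 0.056; 0.0463 with TMM scaling). The glutamate dehydrogenase gene gudB (2.35 ± 0.39) and the ornithine aminotransferase gene rocD (2.01 ± 0.24) rose, while the arginase gene rocF (1.03 ± 0.19) and proline dehydrogenase (FORC47_RS25920, 0.87 ± 0.16) turned to -0.38 and -0.54 with equal totals. In cobalamin synthesis 6 of 9 genes rose and 2 fell, and with equal totals 5 and 3 (camera adjusted p = 0.427; 0.0169 with equal totals); the risen genes hemL (2.24 ± 0.40), hemC (2.21 ± 0.33) and hemD (2.20 ± 0.33) serve tetrapyrrole synthesis in general, and a cobalt transporter gene (FORC47_RS03285) fell (-2.40 ± 0.27). Of 21 sulfur amino acid genes 8 rose and 12 fell, and with equal totals 5 and 14 (camera adjusted p = 0.44), with metK at 2.16 ± 0.35, cysK at 2.03 ± 0.32 and cysC at -2.37 ± 0.41 (-1.75 without T1 and -2.99 without T2). Of 17 aromatic amino acid genes 6 rose and 7 fell, and with equal totals 2 and 12 (camera adjusted p = 0.836), with aroE at 2.02 ± 0.29 and trpD at -1.96 ± 0.36. Nitrogen assimilation had 3 of 11 higher and 5 lower, and with equal totals 2 and 8 (camera adjusted p = 0.559). There glnR rose (2.70 ± 0.51), glnA was at 2.71 ± 0.74 (adjusted p = 0.211 without T1 and 0.174 without T2), and a formate/nitrite transporter gene (FORC47_RS18305) fell (-2.42 ± 0.34).

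Of 29 iron uptake genes 11 rose and 11 fell, and with equal totals 1 rose and 20 fell (camera adjusted p = 0.809); the heme-binding gene isdE fell (-2.22 ± 0.26) and a siderophore-binding gene (FORC47_RS26350) rose (2.03 ± 0.29). Of 15 purine synthesis genes 5 rose and 6 fell (6 and 7 adjusted over the list alone), and with equal totals 3 and 11 (camera adjusted p = 0.836). The median was -0.0211 and the mean 0.26, which differ in sign, and camera's direction was down. There guaA rose (1.99 ± 0.37) and guaB was at 2.63 ± 0.60, with adjusted p = 0.121 without T1 and 0.0814 without T2. In pyrimidine synthesis 5 of 12 genes rose (4 adjusted over the list alone) and 1 fell, and with equal totals 2 rose and 9 fell, while without C0 only 3 rose (camera adjusted p = 0.165), with pyrG at 2.03 ± 0.38, and pyrR at 1.30 ± 0.18, or -0.11 with equal totals. The 2 features named pyrH went apart, at 2.61 ± 0.47 (FORC47_RS19720) and -1.45 ± 0.27 (FORC47_RS09025). Of 32 phage and mobile element genes 10 rose and 15 fell, with equal totals 1 and 23, and without C0 6 and 8 (camera adjusted p = 0.243), with an integrase gene (FORC47_RS07570) at 2.60 ± 0.33 and tnpB (FORC47_RS18000) at -2.21 ± 0.13. Counts not given otherwise were the same adjusted over the list alone. Ribosomal protein, aminoacyl-tRNA synthetase and biofilm genes had fewer than 4 tested features each and are not analysed here.

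The balance of directions rests on the scaling. At the deposited scaling 51.0% of the changed genes were higher, and with every library set to the same total 18.3% were (705 higher and 3151 lower), because that setting lowers the log2 fold change of the median gene by 1.40. Only increases above that shift stay increases under it, as those of sigB and opuD do. The control libraries were not alike: C1 lay above C0 in 96.8% of the genes that rose and below C0 in 90.04% of those that fell, and T1 lay beyond T2 in the same way for 96.2% and 91.0%. The tmRNA gene ssrA, an abundant stable RNA, took 13.1% and 8.36% of assigned reads in C0 and C1 against 2.27% and 2.22% in T1 and T2. The spread of log2 values across genes was 1.47 and 1.61 (SD) in the controls against 2.55 and 2.28 in the salt libraries. In 557 genes with a log2 fold change below -1 and more than 500 reads in C0, taken with no regard to the test, the SD of C1 minus C0 was 0.0613 on the log2 scale, below the 0.0761 of counting noise. In the same genes the SD of T1 minus T2 was 0.304, above the 0.195 of counting noise, and over all genes the controls differed by more than counting (chi-square per degree of freedom 61.6, and 11.7 between T1 and T2).

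Fold changes rose with expression level (Spearman's rho 0.673 across genes, which are not independent replicates). The mean level holds the salt values, which favours a positive rho; with the level taken from the control libraries alone, which favours a negative one, rho was 0.359. Of the 15 lists called by camera, 4 had medians outside the range of 10000 random lists matched on level after adjustment: sporulation and germination (adjusted p = 0.006), branched-chain amino acid synthesis (0.006), cell division (0.0276) and cold shock proteins (0.008). They were outside with the control level too (adjusted p from 0.003 to 0.004). Genes of the random lists were drawn independently, so the range may be too narrow for lists whose members move together. The medians of 6 lay inside the central 95% of random lists matched on either level: chaperones, the tricarboxylic acid cycle, the respiratory chain, cell wall, histidine synthesis and polyhydroxyalkanoates.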

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

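The log2 values as deposited (pseudocount 4) and limma voom on recovered reads were chosen after seeing the data; all other settings were planned. The 3809 changed genes were 3745 to 3858 under every setting with all 4 libraries, and 2917 to 3997 with a library left out; genes changed at least 2-fold were 2266 to 2883, the share higher 47.98% to 54.79% and lists called 11 to 14 in those fits. TMM scaling gave 45.46% higher, with a shift of -0.22 in the median gene. With equal totals 18.28% of changed genes were higher, by the construction of that setting, which moves the median gene by -1.40. Camera with an estimated correlation called 0 lists (smallest adjusted p 0.70), where few residual degrees of freedom left it little power. The fry directional test called 0 (smallest adjusted p 0.0549, with 22 lists at an unadjusted p below 0.05, and 30 by its mixed test).

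Equal totals turned 15 of 146 named genes, by the same shift: rocF (-0.38), putP FORC47_RS06355 (-0.74), phaQ (-0.82), phaR (-0.0215), FORC47_RS06835 (-0.34), FORC47_RS06850 (-0.0762), hisB (-0.57), hisH (-0.87), hisC FORC47_RS07860 (-0.18), hisC FORC47_RS15080 (-0.78), FORC47_RS15250 (-0.65), proB (-1.03), proC FORC47_RS15265 (-0.17), pyrR (-0.11) and FORC47_RS25920 (-0.54). It turned 9 of 30 list medians: cell wall (-0.0446), compatible solute synthesis (-0.65) and uptake (-0.74), histidine (-0.98), motility (-0.18), polyhydroxyalkanoate (-0.34), pyrimidine (-1.08), respiratory chain (-0.68) and sodium-proton antiport (-1.14). The purine median turned to 0.000987 without T1 and was as low as -0.0432 without T2; the cause was not tested. Calls of named genes were lost in 6 cases without C0, 5 without C1, 22 without T1, 18 without T2, 15 with equal totals, 3 with TMM scaling and 1 with no filter; pseudocounts, no trend, deposited values and voom lost 0 of 145, and the filter of 50 lost 0 of the 144 that pass it. Of the calls lost without T1 or T2, 0 had a fold change that moved by more than 1.5 times. No paired analysis was possible because the columns C0, C1, T1 and T2 share only the number 1. The planned count-model tests on recovered reads, an edgeR quasi-likelihood test and a DESeq2 Wald test, were not run.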

Other observations

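All tests reported here, and the genes named here outside the fixed rule, were chosen after the results were seen. The 11 genes of NADH-quinone oxidoreductase, the proton-pumping entry complex of the respiratory chain, all fell (median log2 fold change -0.99), with nuoH at -1.89 ± 0.23, nuoD at -1.82 ± 0.26 and nuoL at -1.43 ± 0.21. In a screen of product words the word NADH-quinone had an adjusted p of 0.0028 over 638 tests (Fisher's exact test). That test treats genes as independent, though the locus tags of these 11 follow each other (FORC47_RS27305 to FORC47_RS27355). Its p-value may therefore be too small. With equal totals the median of the 11 genes was -2.38. Of 12 exosporium and collagen-like genes, named for the outermost spore layer, 10 fell, but the group was put together after such genes were seen among the largest decreases. The word exosporium alone did not pass (adjusted p = 0.167 over 638 word tests). The gene exsE was at 1.24 ± 0.23, and with equal totals 0 of the 12 were above 0. Of the 638 tests 22 passed. Transporter (227 of 430 lower, adjusted p = 8.91e-07), hypothetical (235 of 452 lower, 1.53e-06) and flagellar (25 of 28 higher, 1.77e-05) were among the strongest, while 16 of 18 genes with the word coat fell (adjusted p = 0.00182) and 13 of 14 with repressor rose (0.00551).

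Enterotoxin-named genes rose in 6 of 8 cases, among them hblC (2.21 ± 0.27), hblD (1.91 ± 0.26) and nheA (1.45 ± 0.20), but the group did not pass Fisher's exact test against other genes (adjusted p = 0.196 over 14 tests), and with equal totals 5 of 8 stood above 0. All 5 genes of the branched-chain keto acid and butyrate branch rose, though the group did not pass that test (adjusted p = 0.0537), with bfmBAA at 2.87 ± 0.54 and buk, the butyrate kinase gene, at 2.84 ± 0.61. Stable RNAs went apart: the signal recognition particle RNA ffs (-1.60 ± 0.56) and the 6S RNA ssrS (FORC47_RS08165, -2.25 ± 0.42) fell, a second ssrS feature (FORC47_RS08160, -1.90 ± 0.81, adjusted p = 0.0792) did not pass, the ribonuclease P RNA rnpB was at 2.91 ± 0.87, and ssrA, at 358311 ± 60942 (SD, n = 2) in the controls and 204136 ± 32891 at 8% salt, was not past the threshold (-0.81 ± 3.34, adjusted p = 0.832).

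Libraries of one group differed along the axis that separated the groups. Counts of C1 were described by a mixture of C0 and T1, with 29.2% of its reads from T1. The median squared residual was 0.752 times counting noise, against 4.29 for C0 alone. A mixture of C0 and T2 described C1 about as well (0.779, with 32% of reads from T2). T2 as a mixture of C0 and T1 (7.77% from C0) came to 1.65 against 11.0 for T1 alone, and as a mixture of C1 and T1 (10.6% from C1) to 1.69. The fits therefore fix neither the source library nor its share. More genes than counting noise leaves lay over 4 SD from the mixture. These were 129 of 4718 in C1 (2.73%, against 23.7% from C0 alone) and 180 of 4602 in T2 (3.91%, against 23.4% from T1 alone). So 2 shared read profiles in different proportions may account for much of the spread, but not for all of it. An even background of reads in the controls, fitted as a dilution factor and a constant level, accounted for 52.8% of the variance of fold changes. The salt values enter both the fold changes and the fitted ones, which can raise that share, so it cannot decide. In 63 genes the control value was more than 4-fold above the fit. Such a background stays open, also because gene lengths were not used. Whether the 2 shared profiles come from cells in 2 states, from mixed RNA or from library handling was not tested, and a salt effect stays open too.

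List medians went with expression level, and the trend of fold change with that level may account for part of them. The medians of 6 called lists lay inside the central 95% of random lists matched on either level, as that trend predicts. For 4 called lists (cell division and cold shock, which rose, and sporulation and branched-chain amino acid synthesis, which fell) the medians lay outside after adjustment with either choice of level. The random lists were drawn gene by gene, while the members of these 4 lists had estimated correlations from 0.286 to 0.984. The random range may be too narrow for such lists, so whether the trend is the whole account is not settled. The remaining 5 (SigB, oxidative stress, motility, glycolysis and the ATP synthase) were outside only before adjustment (adjusted p from 0.057 to 0.105) and, with the level taken from the controls alone, also after it (adjusted p from 0.004 to 0.0156), so they cannot be told apart from the trend while the choice of level decides. An effect of salt on these lists stays open as untested.

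A run of 18 tested features, next to each other in the order of locus tags from FORC47_RS28770 to FORC47_RS28870, fell together, each with a log2 fold change of -2 or lower (median -2.92), and names a MobP2 relaxase, VirB4 and a conjugative DNA transfer protein. Chance placement of single fallen genes is argued against, since none of 9999 shuffled gene orders held a run as long. The permutation test gave p = 0.0001, the smallest it can give, and the longest shuffled run was 6. The shuffles moved genes singly, so neighbours that share a transcript were not allowed for. With the level trend removed the median was -4.09 (-4.96 with the control level). The run was picked for fold changes of -2 or lower, so a value below 0 was largely fixed and cannot decide on the trend. Fewer DNA copies of a mobile element under salt stress may lower all its genes alike, but copies were not measured. The SD of fold changes within the run was 0.437, over a range from -3.56 to -2.03, against a median standard error of 0.36. That error holds the difference of T1 from T2 that these genes shared (median -0.96), so it does not measure the spread between genes. The cut at -2 also narrows the SD, so this comparison cannot decide on copies. T1 was below T2 in 18 of 18 of these genes, and lower transcription at 8% salt stays open as untested.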
